A study of Mus musculus with 9 samples.

How the data were processed

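Total RNA from mouse liver was reverse transcribed, amplified, labelled with biotin and hybridised to Affymetrix GeneChip arrays, per the labels' protocols. The 9 arrays analysed carry the label control (4 arrays) or HFD (5 arrays). Replicates were numbered in the order of deposition, which names an array and pairs none. The labels give no scan date or batch, so that no batch could be entered in a fit.

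The deposited values were used as given. Per the series' design text, the authors summarised probes with RMA, quantile normalized the arrays and moved each probe set to a baseline, its median over all samples, and the submitters' processing notes name RMA without a version. RMA returns log2 values, and the deposited values ran around 0 with both signs, so that they were read as log2 differences from the baseline of each probe set, although no log base is stated in the sources used here. In 92.8% of probe sets a pair of values in the middle of the 9 arrays mirrored each other around 0 (within 1e-05), which places the baseline at the median of 10 arrays, 9 of which were analysed here, and the other 7.17% allow the same. Centring removes levels and leaves differences between groups as they were, so that no filter on low signal could be applied and weakly expressed probe sets stayed in.

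The table held 41842 probe sets, of which 60 control probe sets were left out. The annotation paired 32801 probe sets with 1 gene symbol, 862 with several and 8119 with none. Of the named ones 32614 matched the current gene table by Entrez ID, and 0 symbols changed. Probe sets with several symbols or none gave no named result. Of the 17514 genes, 8404 had several probe sets, and the one with the largest standard deviation over all 9 arrays stood for the gene. The choice does not use the group labels but favours the most variable probe set. A difference between the groups adds to this standard deviation, so that the choice also favours larger differences. For 20 named genes the difference was over 1.5 times that with probe sets averaged. Of the 917 genes past the threshold, 542 had several probe sets. In 371 of these all probe sets had the same sign, in 152 another probe set was also past the threshold in the same direction, and in 1 a probe set was past it in the opposite direction. Some genes of the lists are not analysed here, and the counts of each list are over its measured members.

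HFD was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a mean-variance trend, two-sided, Benjamini-Hochberg over all 17514 genes, threshold 0.05), with no covariate. Gene lists fixed before the data were examined, 48 in all and covering pathways of liver metabolism, stress, immunity and markers of cell types, were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated per list (median 0.144), and with fry, which tests whether a list moves one way on balance without setting it against other genes. Each list was also given 1 value per array, the mean of its members, and tested by exact permutation over all 126 splits of the arrays, two-sided. The smallest p this allows is 0.0159.

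Genes named in the text follow a rule fixed before the data were examined. They are the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, leaving out clone names, the 4 members of each list with the lowest p, and the list of lipid genes linked to miR-27b in full. Ebp and Sc5d were named in addition after their values were seen, as the members of the cholesterol synthesis list that did not pass.

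The fit was tested on simulated data with the spread of the real genes and the same 4 and 5 arrays, in which 200 of 17514 genes were changed. Over 20 simulations of HFD against control, 97.6% of changes of 2 on the log2 scale were recovered, 86.0% of changes of 1 and 38.7% of changes of 0.5, and 4.58% of all calls were false (1.34% to 7.45% per simulation). A separate simulation with another seed gave 9.66% false calls. With no list moved, camera called a list in 1 of 20 simulations, each gene varying independently of the others.

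Alternatives tried were subtraction of each array's median, a further quantile normalization, averaging of probe sets, leaving out the 25% of genes with the smallest standard deviation, robust eBayes, array weights, leaving out each array in turn, every probe set on its own, an adjusted p under 0.01, a change of at least 1.5-fold, an unmoderated test, an estimated correlation, fry and the median in place of the mean of a list. Added after seeing the data were leaving out probe sets whose names end in _x_at or _s_at, which can bind related transcripts, and leaving out HFD replicate 5 with control replicate 1. No scaling moved the median difference of all genes (-0.02) by over 0.1. The closing section gives their effect.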

Results

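Liver mRNA was profiled on Affymetrix GeneChip arrays from c57Bl/6 mice given either a control diet or a high-fat diet (HFD) that held 21% fat and supplied 42% of its calories from fat. The labels place 4 arrays in the control group and 5 in the HFD group, and the comparison asks which liver transcripts differed with the diet. Values were available for 41782 probe sets per array after control probe sets were left out, and 17514 genes were tested. Each value is a log2 difference from the baseline of its probe set, so that differences between groups can be read while absolute levels cannot. The number of arrays limits the precision. The labels give no sex, age, time on diet or batch, and do not say that each array is a separate animal, so that p-values measure only the spread between these arrays, which may be technical. Differences below are HFD minus control on the log2 scale, with the standard error of the fit, for 4 control and 5 HFD arrays.

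Genes of cholesterol synthesis fell in the HFD group, and their mean difference was the largest of the 48 lists examined. Of the 17 measured members of the list, 15 fell and none rose. Sqle, the squalene epoxidase, fell by 4.14 ± 0.22 (17.6-fold), Idi1, an isomerase of the isoprenoid steps, fell by 3.58 ± 0.18, and Cyp51, the lanosterol demethylase, fell by 2.90 ± 0.20 (7.47-fold). Msmo1, a methylsterol oxidase, fell by 2.81 ± 0.23, Fdft1, the squalene synthase, fell by 2.26 ± 0.15, and Fdps, which makes farnesyl diphosphate, fell by 2.26 ± 0.29. The remaining members, Ebp (-0.54 ± 0.18) and Sc5d (-0.24 ± 0.28), were not past the threshold over all genes, and with p-values adjusted over the list alone 16 members fell.

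The mean of the cholesterol synthesis list was 1.34 ± 0.18 (SD, n = 4) in control and -0.47 ± 0.26 (SD, n = 5) in HFD, and the arrays of the groups did not overlap. The list was lower by camera, with an adjusted p of 1.83e-27 at the preset correlation and an adjusted p = 0.0824 with an estimated correlation. Averaging all probe sets brought the differences of Msmo1 and Fdft1 to -1.41 and -1.09, both still past the threshold.

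**Figure D1:**
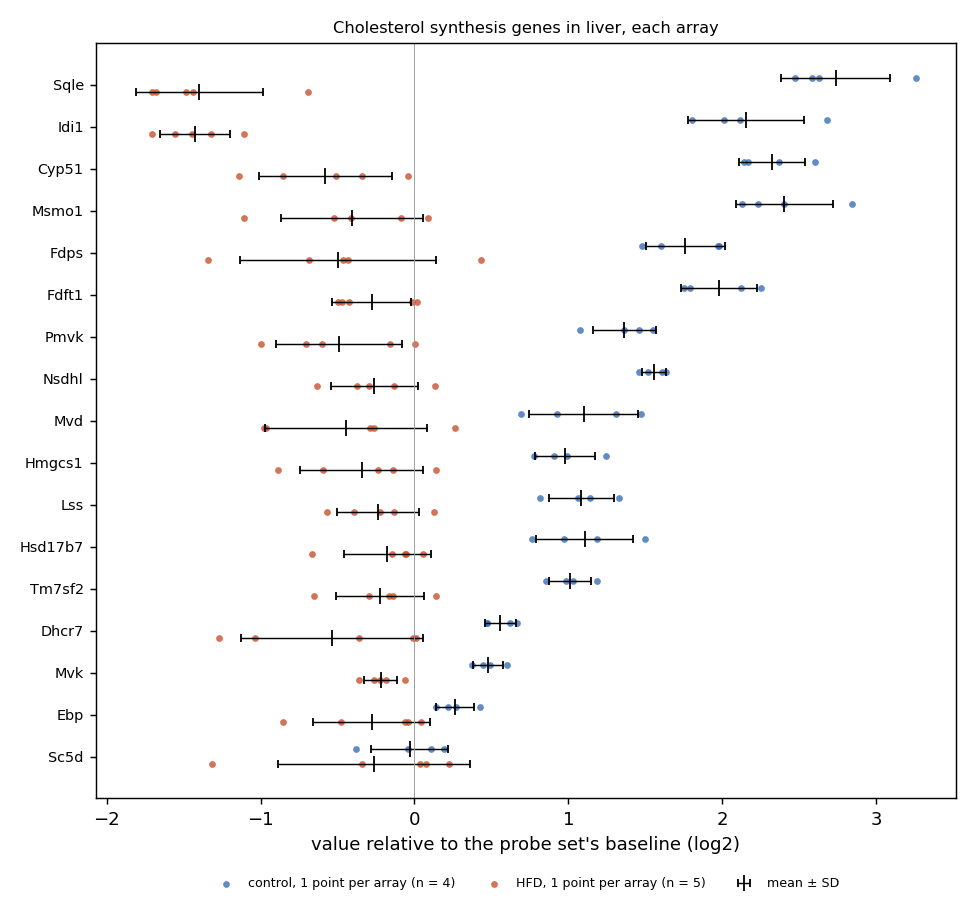
Values of the 17 measured cholesterol synthesis genes on each array, relative to the baseline of each probe set (log2, horizontal axis), with 4 control arrays in blue, 5 HFD arrays in orange, and black bars for the mean ± SD. HFD arrays lie to the left of control arrays for all genes except Sc5d, whose groups overlap, and the largest difference of means is that of Sqle (-4.14), with a gap of 3.16 between its nearest arrays.

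Other sterol genes moved in both directions. Abcg5 and Abcg8, whose products form the transporter that exports sterols into bile, rose by 1.99 ± 0.20 and 1.48 ± 0.16, and Srebf1, which encodes a transcription factor of lipid synthesis, rose by 1.54 ± 0.26. These were 3 of the 9 measured members of the list of sterol efflux and LXR targets, none fell, and Pltp had a difference of -1.25 ± 0.36 that did not pass (adjusted p = 0.0742). The list as a whole was not past the threshold (camera adjusted p = 0.209), and adjusted over the list alone 3 members rose and 2 fell. In the list of sterol uptake and SREBP2 control, Srebf2, which encodes the transcription factor that drives cholesterol synthesis, fell by 0.81 ± 0.14, and Insig2, whose product retains that factor in the endoplasmic reticulum, rose by 1.08 ± 0.14. Stard4 (-1.13 ± 0.30) and Lipa (0.86 ± 0.23) did not pass over all genes, the camera adjusted p of the 9 measured members was 0.610, and adjusted over the list alone 3 rose and 4 fell.

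Genes of triglyceride synthesis and lipid droplets rose in the HFD group, 11 of 23 measured members, with none lower. Cidec and Cidea, whose products coat lipid droplets and promote their growth, rose by 2.25 ± 0.38 (4.77-fold) and 1.85 ± 0.33 (3.60-fold). Mgll, the monoglyceride lipase, rose by 1.41 ± 0.20, and Agpat2, an acyltransferase of triglyceride synthesis, by 0.77 ± 0.08. In camera the adjusted p was 9.90e-08, and an adjusted p = 0.179 with an estimated correlation. Adjusted over the list alone 12 members rose and 1 fell. The count of 11 fell to 6 without control replicate 2, control replicate 3 or HFD replicate 3. Cidec was also the only one of the 8 measured adipose markers past the threshold, and that list was not called by camera (adjusted p = 0.149). Its array means did not overlap (exact permutation p = 0.0159, adjusted p = 0.0476), and fry called it higher (adjusted p = 0.0385). Car3, another adipose marker, had a difference of 3.26 ± 1.20 that did not pass (adjusted p = 0.162), and adjusted over the list alone 1 adipose marker rose.

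Within the list of PPARgamma targets and fatty acid uptake, 7 of 15 measured members rose and 1 fell. Cidea and Cidec stand in this list as well as in that of lipid droplets, so that the calls of these lists are not independent. Cd36, which encodes a fatty acid transporter of the cell surface, rose by 2.42 ± 0.29 (5.34-fold), and Fabp2, a fatty acid binding protein, by 1.79 ± 0.13 (3.46-fold). Fabp5, another fatty acid binding protein, fell by 3.52 ± 0.49 (11.5-fold). Camera gave an adjusted p of 2.63e-05, with an adjusted p = 0.167 with an estimated correlation, and adjusted over the list alone 8 rose and 1 fell. In the list of lipid genes linked to miR-27b, of which 2 members were measured, Pparg, the nuclear receptor of fat storage, rose by 0.82 ± 0.16 (adjusted p = 0.0183) and Gpam differed by -0.01 ± 0.34 (adjusted p = 0.989). That list was not called (camera adjusted p = 0.200), and adjusted over the list alone 1 member rose.

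Fatty acid synthesis genes rose in 4 of 20 measured members, with none lower. Elovl6, which elongates saturated fatty acids, rose by 1.95 ± 0.28 (3.87-fold), Scd1, the main liver desaturase, by 1.32 ± 0.30, and Pklr, the liver pyruvate kinase, by 1.28 ± 0.25, beside Srebf1. By camera, the adjusted p was 5.42e-05, with an adjusted p = 0.321 with an estimated correlation, and adjusted over the list alone 9 rose. The array means of this list overlapped between the groups (exact permutation adjusted p = 0.0762), and fry did not call it (adjusted p = 0.0668). Averaging all probe sets brought Elovl6 to 1.15 and Scd1 to 0.82, and 2 members rose without control replicate 2, 3 or 4. In the list of glycolysis and fructolysis, 4 of 10 measured members rose, namely Pklr, Khk (0.71 ± 0.11), Slc2a2 (0.47 ± 0.10) and Gckr (0.35 ± 0.08), which is also the count adjusted over the list alone. Khk encodes the kinase of fructose breakdown and Slc2a2 the glucose transporter of hepatocytes. Without control replicate 2, 3 or 4 only 1 member passed. The camera adjusted p was 0.00813, and an adjusted p = 0.253 with an estimated correlation.

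Some genes of fatty acid oxidation and ketogenesis rose. Of 19 measured genes of peroxisomal and omega oxidation 6 rose and none fell, led by Aldh3a2 (1.13 ± 0.15), a fatty aldehyde dehydrogenase, and Decr2 (1.00 ± 0.15), a peroxisomal reductase of unsaturated acyl-CoA, with Acaa1a (0.59 ± 0.13) and Acaa1b (0.43 ± 0.09), the peroxisomal thiolases. Of 17 measured genes of mitochondrial beta-oxidation 4 rose and none fell, which were Hadh (0.60 ± 0.10), Decr1 (0.49 ± 0.12), Eci1 (0.48 ± 0.10) and Slc25a20 (0.42 ± 0.08), the carnitine carrier. Of 12 measured genes of ketogenesis and PPARalpha targets 4 rose and none fell, namely Vnn1 (1.83 ± 0.25), Ppara itself (1.34 ± 0.27), Bdh1 (1.27 ± 0.10), which interconverts ketone bodies, and Acat1 (0.54 ± 0.10). Camera gave an adjusted p of 6.35e-05 for the peroxisomal list, 0.000215 for the mitochondrial list and 0.00282 for the ketogenic list. These calls were lost at an adjusted p = 0.167, an adjusted p = 0.184 and an adjusted p = 0.163 with an estimated correlation, in the same order. Array means overlapped for the mitochondrial list (exact permutation adjusted p = 0.0914), where HFD replicate 5 lay among the controls, and not for the other lists. Adjusted over the list alone, 8 peroxisomal members rose and 1 fell, 7 mitochondrial members rose and 5 ketogenic members rose. Without control replicate 2, each of these lists had 2 members higher. The peroxisomal count was also 2 without control replicate 3 and 3 without HFD replicate 3, and the mitochondrial count 2 without control replicate 3, control replicate 4 or HFD replicate 3.

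Among genes of bile acid synthesis and transport, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.63 ± 0.30 and Cyp7b1, an oxysterol hydroxylase, fell by 1.90 ± 0.41. Abcb4, the phospholipid exporter of bile, rose by 0.53 ± 0.10 and Abcc2, an organic anion exporter, by 0.43 ± 0.09. The other 19 of 23 measured members did not pass, the list was not called (camera adjusted p = 0.213), and adjusted over the list alone 2 rose and 3 fell. Averaging all probe sets brought Cyp7b1 to -1.25, still past the threshold. The call of Cyp7b1 ended when any 1 control array or HFD replicate 3 was left out, and without HFD replicate 5 and control replicate 1 together (highest adjusted p = 0.0919). In the bile acid list the lower count was 1 when any 1 control array or HFD replicate 3 was left out, and the higher count was 1 without control replicate 2, control replicate 4 or HFD replicate 3. Among apolipoproteins and genes of lipoprotein handling, 3 of 20 measured members rose and 2 fell. Apoa4, which encodes apolipoprotein A-IV, rose by 3.09 ± 0.43 (8.52-fold), Apob by 1.27 ± 0.18 and Apoc2 by 1.13 ± 0.14, whereas Apom fell by 1.26 ± 0.20. Averaging all probe sets brought Apob to 0.71, still past the threshold. The apolipoprotein list had a camera adjusted p of 0.193. The arrays of the groups did not overlap in its mean (exact permutation p = 0.0159, adjusted p = 0.0476). Fry called it higher (adjusted p = 0.0103), and adjusted over the list alone 5 rose and 3 fell.

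The largest rise of all named genes was that of Cyp2b9, a female-biased cytochrome P450, at 4.19 ± 0.68 (18.2-fold, adjusted p = 0.00760). HFD replicates 1 and 2 stood at 0.16 and -0.16, and HFD replicates 3, 4 and 5 at 3.28, 3.16 and 1.95, with controls between -2.78 and -2.19. Of 13 measured female-biased liver genes 2 rose, Cyp2b9 and Sult1e1 (0.58 ± 0.15), an oestrogen sulfotransferase, and none fell. Cyp2b13 (0.55 ± 0.16) and Acot3 (0.58 ± 0.20) did not pass. Of 12 measured male-biased liver genes 5 fell and none rose, among them Ugt2b38, a glucuronosyltransferase, by 2.77 ± 0.39 (6.80-fold), Cyp7b1, the complement gene C6 by 0.91 ± 0.15 and Gstp1 by 0.73 ± 0.13. Xist differed by -0.15 ± 0.11 and the Y-linked genes Kdm5d, Uty and Eif2s3y by 0.25 ± 0.15, 0.38 ± 0.25 and -0.22 ± 0.15, none past the threshold (camera adjusted p = 0.971 for the 4 sex chromosome genes, with no member past it adjusted over the list alone).

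In camera the adjusted p was 2.48e-06 for the male-biased list and 0.0238 for the female-biased list, with an adjusted p = 0.252 with an estimated correlation for the first and an adjusted p = 0.258 with an estimated correlation for the second. Adjusted over the list alone, 7 male-biased genes fell and 3 female-biased genes rose. The male-biased count of 5 was 3 when any 1 control array or HFD replicate 3 was left out, and the female-biased count of 2 was 1 without any 1 array other than HFD replicate 3. The female-biased call ended under array weights (adjusted p = 0.0579), without probe sets that can bind related transcripts (adjusted p = 0.0501) and without HFD replicate 5 and control replicate 1 together (adjusted p = 0.0566). Cyp2b9, Ugt2b38 and Hsd3b3 belong to families of similar genes, so that their probe sets may also bind relatives.

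Other genes with large changes included Hsd3b3, a hydroxysteroid dehydrogenase (2.42 ± 0.43), Cyb5r3, a cytochrome b5 reductase (2.34 ± 0.27), Wfdc2 (2.30 ± 0.27), Tmie (1.88 ± 0.26) and Rgs5, a regulator of G-protein signalling (1.87 ± 0.26), all higher in HFD. Lower in HFD were Socs2, a suppressor of cytokine and growth hormone signalling (-2.98 ± 0.50), the pseudogene Serpina4-ps1 (-2.74 ± 0.38), Csad, an enzyme of taurine synthesis (-2.59 ± 0.21), Egfr, the epidermal growth factor receptor (-2.52 ± 0.39), and Scara5, a ferritin receptor (-2.31 ± 0.45). For several of these the size depended on the probe set, and for Hsd3b3 and Cyb5r3 the sign did too. A rise was seen in only 1 of the 2 probe sets of Hsd3b3 and in 3 of the 4 of Cyb5r3. With all probe sets of a gene averaged the differences became 0.74 for Cyb5r3, 0.81 for Rgs5, 1.21 for Tmie, -1.45 for Socs2, -1.33 for Egfr and -1.29 for Scara5, all past the threshold, and 1.14 for Hsd3b3, which was not (adjusted p = 0.0587).

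**Figure D2:**
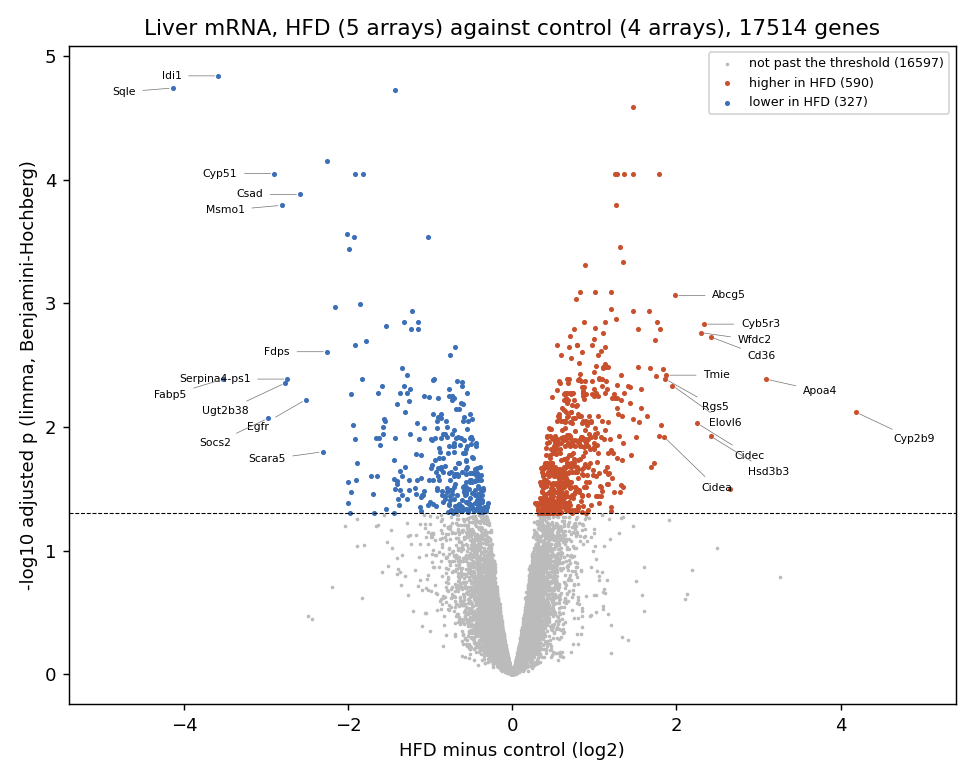
Log2 difference HFD minus control (horizontal axis) against -log10 of the adjusted p (vertical axis) for 17514 genes, with 590 genes higher in HFD in orange, 327 lower in blue, the rest in grey, and the adjusted p of 0.05 as a dashed line. The 24 labelled genes are the 12 largest rises and the 12 largest falls named by the rule for genes past the threshold whose groups did not overlap, clone names left out, so that some unlabelled falls exceed labelled rises in size. Of the labelled genes, Sqle and Idi1 have the lowest adjusted p of these.

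Genes listed as markers of Kupffer cells, the resident liver macrophages, were lower in the HFD group, though not all need be particular to these cells. Of 15 measured markers 10 fell and none rose, including Vsig4, a complement receptor (-1.89 ± 0.38), the lysozyme gene Lyz2 (-1.62 ± 0.30), Folr2 (-1.25 ± 0.22) and Timd4 (-1.16 ± 0.20). The mean of the list was 0.74 ± 0.46 (SD, n = 4) in control and -0.54 ± 0.52 (SD, n = 5) in HFD. HFD replicate 4 (0.15) lay above control replicate 4 (0.13), so that the groups overlapped. The count of 10 moved with single arrays. It was 2 without control replicate 2, and 3 without control replicate 1, control replicate 3 or HFD replicate 3. Without HFD replicate 2 it was 5, without HFD replicate 1 it was 6, and without control replicate 4 it was 13. Under array weights 13 markers passed, and 12 after a further quantile normalization. The camera adjusted p was 1.10e-10, with an adjusted p = 0.253 with an estimated correlation, and adjusted over the list alone 14 members fell.

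Genes of antigen presentation by MHC class II fell with the Kupffer cell markers, 6 of 8 measured members, including H2-Ab1 (-1.58 ± 0.27), Ctss (-1.36 ± 0.28), the invariant chain gene Cd74 (-1.35 ± 0.29) and H2-Eb1 (-0.94 ± 0.17). By camera, the adjusted p was 1.47e-06, with an adjusted p = 0.184 with an estimated correlation, and adjusted over the list alone 7 fell. The count of 6 was 2 without control replicate 1, control replicate 2 or HFD replicate 3, and 3 without control replicate 3. Of 17 endothelial markers 3 fell, Fcgr2b (-2.00 ± 0.44), Flt4 (-1.03 ± 0.25) and Stab1 (-0.82 ± 0.20), and Bmp2 had a difference of -0.66 ± 0.17 (adjusted p = 0.0555). The camera adjusted p of the endothelial list was 3.56e-07, with an adjusted p = 0.300 with an estimated correlation, and adjusted over the list alone 12 fell. The arrays of the groups overlapped in the mean of the endothelial list, and fry did not call it (adjusted p = 0.0579). No endothelial marker passed in limma when any 1 control array or HFD replicate 3 was left out, 1 passed without HFD replicate 2 or HFD replicate 5, 5 without HFD replicate 1 and 9 without HFD replicate 4.

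Among 12 neutrophil markers only S100a9 passed, falling by 1.97 ± 0.45. S100a8 (-2.04 ± 0.56), Camp (-0.21 ± 0.07) and Mmp8 (-0.24 ± 0.09) did not, and adjusted over the list alone 2 fell. S100a9 did not pass when any 1 control array, HFD replicate 2 or HFD replicate 3 was left out, or HFD replicate 5 and control replicate 1 together (highest adjusted p = 0.0915). In camera the adjusted p was 0.0174, with an adjusted p = 0.167 with an estimated correlation, and the call ended without control replicate 3 (adjusted p = 0.0504) and without probe sets that can bind related transcripts (adjusted p = 0.0501), where the mean of the list went from -0.41 to -0.26. Of 13 markers of recruited and lipid-associated macrophages only Fabp5 passed. Cd9 (-0.78 ± 0.21), Gpnmb (0.29 ± 0.18) and Itgax (-0.18 ± 0.15) did not, the camera adjusted p was 0.431, and adjusted over the list alone 2 fell.

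No marker of T and NK cells (16 measured, camera adjusted p = 0.429), of B cells and plasma cells (13 measured, 0.486), of erythroid cells (8 measured, 0.988) or of exocrine pancreas (10 measured, 0.660) passed the limma test, and none passed adjusted over the list alone. Gzma (-0.19 ± 0.09), Xbp1 (-0.85 ± 0.27), Alas2 (0.27 ± 0.10) and Cela1 (-0.87 ± 0.29) had the lowest p in these lists. Of 25 genes of stellate cells and fibrosis, Lrat, which stores retinol as esters, rose by 0.71 ± 0.17 and Reln fell by 0.53 ± 0.13, Lum stood at -0.96 ± 0.27 and Tgfbi at -0.68 ± 0.20, and the list was not called (camera adjusted p = 0.431, with 1 higher and 5 lower adjusted over the list alone). It was called lower under array weights (mean -0.21, adjusted p = 0.0346) and without HFD replicate 4 (-0.19, adjusted p = 0.0470), and its mean was 0.06 without HFD replicate 2. Reln did not pass in limma with its probe sets averaged (-0.30, adjusted p = 0.0527). Of 10 cholangiocyte markers Krt23 rose by 0.69 ± 0.09 and Pkhd1 stood at 0.72 ± 0.20 (camera adjusted p = 0.449, with 2 higher adjusted over the list alone). Of 14 hepatocyte markers only Hnf4a passed, falling by 0.91 ± 0.19. Tat (-0.79 ± 0.22), Fgb (-0.37 ± 0.11) and Ahsg (-0.21 ± 0.07) did not, and adjusted over the list alone 4 fell. The hepatocyte list had a camera adjusted p of 0.0403, with an adjusted p = 0.364 with an estimated correlation, and the call ended without control replicate 1 (0.0588), control replicate 3 (0.0771), HFD replicate 3 (0.0651) or HFD replicate 4 (0.0576), without HFD replicate 5 and control replicate 1 together (0.0711), and under array weights (0.0627). Hnf4a was no longer past the threshold without probe sets that can bind related transcripts (-0.52, adjusted p = 0.306), nor without control replicate 2, 3 or 4 or HFD replicate 3.

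Few inflammatory genes passed singly. Of 22 inflammatory cytokines and NF-kB targets only Il1r1 passed, falling by 1.69 ± 0.43, with Vcam1 (-1.48 ± 0.41), Cd14 (-0.98 ± 0.28) and Il1b (-0.59 ± 0.17) not past the threshold and 5 lower adjusted over the list alone. Of 24 acute phase genes 4 fell and 1 rose. Itih3 (-1.08 ± 0.16), Apcs (-1.02 ± 0.16) and Orm1 (-0.70 ± 0.17) fell beside Il1r1, and Orm3 rose by 1.35 ± 0.30, with 2 higher and 13 lower adjusted over the list alone. The acute phase count of 4 was 2 without control replicate 2, control replicate 3, HFD replicate 1, HFD replicate 2 or HFD replicate 3, and Orm3 did not pass without control replicate 1, 3 or 4, without HFD replicate 3, or without HFD replicate 5 and control replicate 1 together. Of 28 interferon response genes only Igtp passed, falling by 0.40 ± 0.10, and none passed adjusted over the list alone, with Oas2 at -0.26 ± 0.07, Ifit1 at -0.37 ± 0.11 and Oas1a at -0.43 ± 0.14. Camera gave an adjusted p of 0.000371 for the inflammatory list, 7.96e-05 for the acute phase list and 0.000357 for the interferon list. None of these calls held, with an adjusted p = 0.167, an adjusted p = 0.256 and an adjusted p = 0.321 with an estimated correlation, in that order. Array means of the inflammatory list did not overlap, while those of the acute phase and interferon lists did (exact permutation adjusted p = 0.0914 for each), and fry did not call the interferon list (adjusted p = 0.0668).

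Some genes of cytosolic ribosomal proteins were lower by small amounts. Of 30 measured members 9 fell and none rose, among them Rps24 (-0.66 ± 0.13), Rps18 (-0.63 ± 0.10), Rps19 (-0.50 ± 0.08) and Rpl10a (-0.44 ± 0.08), and adjusted over the list alone 22 fell. The mean of the list was 0.22 ± 0.06 (SD, n = 4) in control and -0.16 ± 0.07 (SD, n = 5) in HFD, with no overlap. The camera adjusted p was 1.35e-12, with an adjusted p = 0.0824 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, and without probe sets that can bind related transcripts Rps24 stood at -0.22 (adjusted p = 0.549). Averaging probe sets brought Rps18 to -0.25, still past the threshold. The count of 9 was 2 without control replicate 2, 3 without control replicate 3 or HFD replicate 3, 4 without control replicate 4, 5 without HFD replicate 1 or HFD replicate 2, and 15 after a further quantile normalization.

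**Figure D3:**
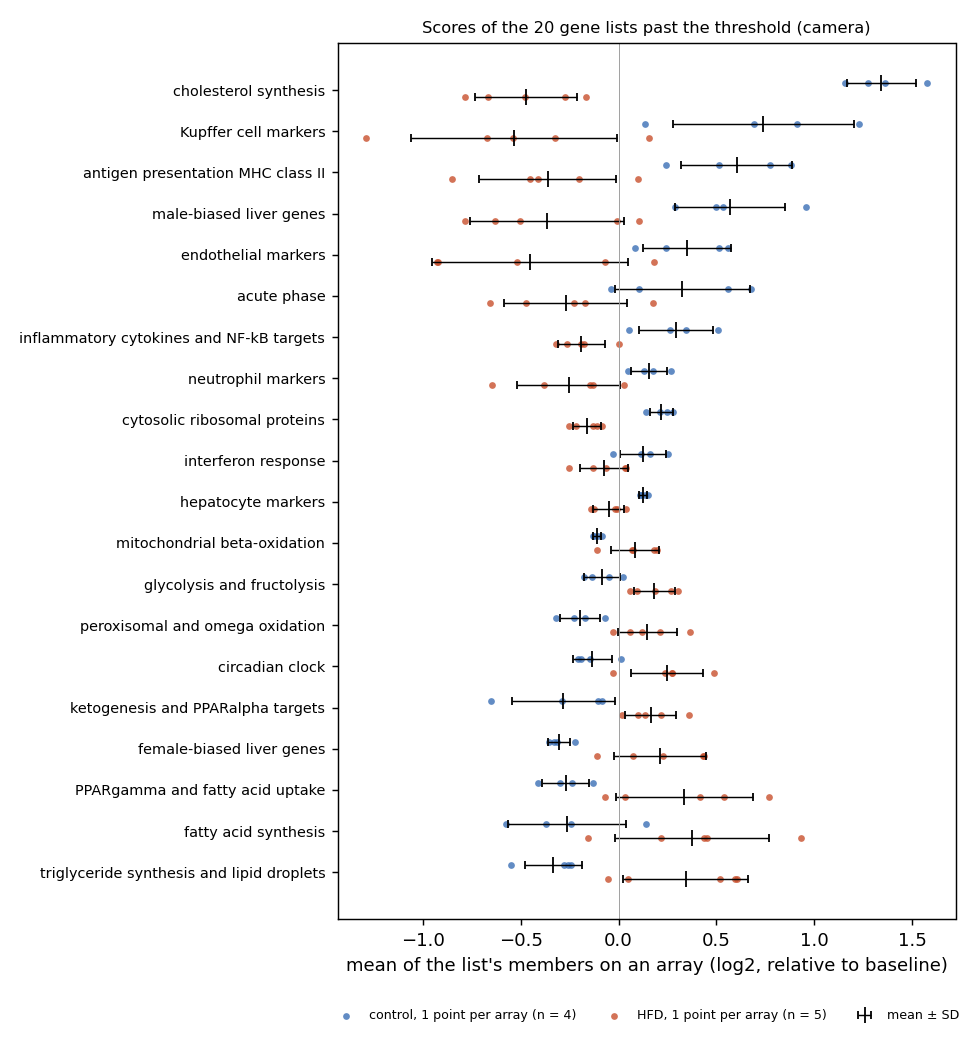
Mean of the measured members of each of the 20 gene lists past the threshold in camera, on each array (log2 relative to baseline, horizontal axis), with 4 control arrays in blue, 5 HFD arrays in orange and black bars for the mean ± SD. Lists lower in HFD stand at the top, led by cholesterol synthesis (control mean 1.34, HFD mean -0.47), and lists higher in HFD at the bottom.

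Other genes of energy and nitrogen metabolism moved singly. Of 36 oxidative phosphorylation genes only Sdhb rose (0.28 ± 0.07), with Ndufb3 at 0.27 ± 0.07, and none passed adjusted over the list alone. Sdhb was also 1 of 18 TCA cycle genes, of which Ogdh fell by 0.41 ± 0.10, and Pdhb stood at 0.43 ± 0.12, with 2 higher and 1 lower adjusted over the list alone. In camera the adjusted p was 0.0655 for oxidative phosphorylation and 0.583 for the TCA cycle. The oxidative phosphorylation list passed the threshold without HFD replicate 5 (adjusted p = 0.00651), HFD replicate 3 (0.0352) or control replicate 2 (0.0394), without HFD replicate 5 and control replicate 1 together (0.00755), after a further quantile normalization (0.0311), with probe sets averaged (0.0188) and under array weights (0.0113). The TCA cycle list passed with probe sets averaged (0.0243), and Ogdh did not pass with its probe sets averaged (-0.16). Of 15 genes of gluconeogenesis and glycogen, Ugp2 (0.96 ± 0.16) and Pcx (0.67 ± 0.12), the pyruvate carboxylase, rose and Got1 (-1.18 ± 0.27) fell, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.449). Of 17 genes of the urea cycle and amino acid catabolism only Agxt fell (-0.59 ± 0.14), and Hgd (0.89 ± 0.23) and Oat (0.65 ± 0.19) did not pass, with 3 higher and 3 lower adjusted over the list alone (0.988). Of 15 genes of one-carbon and methionine metabolism Sardh rose (0.52 ± 0.09) and Csad fell, Dmgdh stood at 0.32 ± 0.09, and adjusted over the list alone 3 were higher and 1 lower (0.958).

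Drug-metabolising genes also moved singly. Of 21 cytochrome P450 genes of xenobiotic metabolism, Cyp2b9 and Cyp2c38 (1.19 ± 0.22) rose, and Cyp2c55 (-1.92 ± 0.14) and Cyp1a2 (-1.53 ± 0.18) fell, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.583). Of 21 genes of conjugation and NRF2 targets, Sult1d1 (1.05 ± 0.16) and Gstt1 (0.54 ± 0.10) rose, Ugt2b5 (-0.44 ± 0.11) fell and Gsta4 stood at -0.54 ± 0.14, with 3 higher and 2 lower adjusted over the list alone (0.498). Of the stress and growth lists, the unfolded protein response had 1 of 22 members past the threshold, Asns (-1.11 ± 0.24), which makes asparagine (camera adjusted p = 0.511). The cell cycle list had 1 of 26, Tk1 (-0.79 ± 0.20, camera adjusted p = 0.611). No member passed the limma test among 10 heat shock genes (0.988), 18 immediate early genes (0.486) or 28 proteasome genes (0.292), where Hsp90aa1 (0.52 ± 0.22), Junb (-0.86 ± 0.24) and Psmd1 (0.23 ± 0.08) had the lowest p. Adjusted over the list alone, 1 unfolded protein response gene and 3 immediate early genes were lower, and none passed in the cell cycle, heat shock or proteasome lists.

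Over all genes, 917 of 17514 were past an adjusted p of 0.05 in limma, 590 higher and 327 lower in HFD, and 3341 had an unadjusted p under 0.05. Of the 917 genes, 227 changed at least 2-fold, 127 higher and 100 lower, and 863 had no overlap between the groups. No overlap was seen for 9.82% of all genes, against the 1.59% that chance gives. Camera called 20 of 48 lists at the preset correlation, 9 higher and 11 lower, and 0 with an estimated correlation. Of these 20 lists, 13 had array means that did not overlap, and the other 7 overlapped and did not pass the exact permutation. By exact permutation of the list means 16 lists passed, each with the smallest exact p the arrays allow (0.0159, two-sided). Adjusted over the 48 lists this became 0.0476, a value set by how many lists share the smallest p. With fewer lists at that p the adjusted value would be higher, so that the 16 calls stand together. The mean, the median and the camera direction of a list differed in sign for 8 lists, none of them called. The gene count fell to 385 without control replicate 2, 474 without control replicate 3, 475 without HFD replicate 3 and 568 without control replicate 4. It was 706 when HFD replicate 5 and control replicate 1, the arrays farthest from the rest of their groups, were left out together, a setting chosen after seeing the data. Of 110 named genes past the threshold, 63 stayed past it under each of up to 17 alternatives of scaling, probe sets, filter, model and arrays, which leave out the stricter thresholds and the unmoderated test. In 37 of 48 lists, leaving out some array moved the count of members higher or lower by over 1.5 times, or from or to 0. The calls of 25 named genes were lost under 5 or more of 17 alternatives, which were Decr1, Agxt, Ugt2b5, Sult1e1, Fcgr2b, Stab1, Flt4, Lrat, Reln, Il1r1, Orm1, Igtp, Tk1, Sdhb, Ogdh, Scd1, Cyp7b1, Got1, Gckr, Igfals, Akt1, Hnf4a, S100a9, Orm3 and Ctss. Those of 22 others were lost under 1 to 4, which were Hsd3b3, Pklr, Hadh, Eci1, Acaa1b, Acaa1a, Acat1, Ppara, Abcb4, Abcc2, Pparg, Slc2a2, Gstt1, Lyz2, Vsig4, Cd74, Asns, Hlf, Ccng1, Casp8, Rpl10a and Rps24.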

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

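The tests on Kupffer cell markers, ribosomal protein genes and sex-biased genes below were chosen only after the results were seen, and the tests against other splits of the arrays before. Each group of 4 or 5 arrays was examined for an array far from the others, as the gap to its neighbour divided by the range of the group, over 48 list means, 189 named genes and 2 array measures. An array stood apart in 21 of 478 groups (4.39%), where chance gives about 5%.

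Chance alone was an unlikely source of the gene count. Splits of the arrays cannot tell the diet from a batch or a processing step that followed the groups. Of 100 splits of the 9 arrays into 4 and 5, the real one included, 1 gave as many as 917 genes, and the highest of the other splits gave 200. For the lists, 2 of 100 splits gave as many as 20, and another split gave 21, the one that exchanged the names of the groups and moved HFD replicate 2 alone to the side of the controls. The other splits had a median of 9 lists. This median is not free of the diet, as many splits still part most HFD arrays from most control arrays. Those run with all 4 control arrays in the group of 5 gave 17 to 21 lists. Those with 2 control arrays in the group of 5 gave 0 to 14. The preset correlation can thus call lists where a split hardly follows the diet. The count of 20 says little about how many lists moved.

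Kupffer cell markers were lower in HFD by a mean of -1.28, though their array means overlapped between the groups (exact permutation adjusted p = 0.0762). A single array did not set the mean difference, since leaving out any array gave -1.48 to -1.09. A fall of stellate cell and fibrosis genes as large as that of the Kupffer markers was argued against. The Kupffer mean less the stellate mean on each array differed by -1.19 between the groups (exact permutation p = 0.0159) and by -1.34 to -0.96 with any 1 array left out. The stellate list also holds fibrosis genes, so that its mean does not measure the share of stellate cells. The lists of cholangiocytes (mean 0.11), T and NK cells (-0.06) and B cells and plasma cells (-0.08) did not fall by as much either. Endothelial (-0.80), neutrophil (-0.41) and recruited macrophage (-0.33) markers were lower, by less than the Kupffer markers. These means argue against a like fall of every cell type other than hepatocytes, as far as the markers show it. Whether weakly expressed markers could show such a fall cannot be judged from centred values. The stellate list itself was lower under array weights (-0.21) and without HFD replicate 4 (-0.19), so that a smaller fall of stellate cell genes stays open. None of the 15 markers stands in another list, but whether hepatocytes or other cells express some of them too cannot be read from centred values. A lower share of Kupffer cells, a lower expression within them, or a loss of macrophages and endothelial cells together may each underlie the difference, as hypotheses, and the endothelial list fell too.

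Cytosolic ribosomal protein genes were lower by a mean of -0.38. Probe sets named _x_at or _s_at were not the whole cause, since 27 members without such probe sets differed by -0.36 (exact permutation p = 0.0159). Whether the other probe sets bind related transcripts too was not tested, as it cannot be judged from their names. Oxidative phosphorylation genes did not fall with them (mean 0.04), and the ribosomal mean less that mean differed by -0.42 (exact permutation p = 0.0159). This contrast cannot decide on a general loss of short, abundant transcripts. The oxidative phosphorylation list was itself called higher under some alternatives, and a rise of that list could hide such a loss. Length and abundance of transcripts were not measured either. An effect of the diet on these transcripts is a hypothesis, and quality of the RNA was not tested.

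Male-biased genes were lower (mean -0.93) and female-biased genes higher (mean 0.52) in HFD. Animals of different sex in the groups were argued against by Xist, which differed by -0.15 (95% interval -0.39 to 0.09), and by the 3 Y-linked genes, whose intervals stayed within 0.92 of 0. Single arrays did not set these means either, since the smallest differences with 1 array left out were 0.46 for the female-biased and -0.80 for the male-biased list. Leaving out 1 array cannot show a difference carried mainly by several arrays. In HFD replicates 1 and 2 the male-biased mean was -0.01 and 0.10, against -0.79, -0.63 and -0.50 in replicates 3, 4 and 5. The female-biased mean was 0.08 and -0.11 against 0.44, 0.43 and 0.23. The counts of members past the threshold did depend on single arrays, as given above. Cyp2b9 makes up much of the female-biased mean, the median of that list being 0.16. A change in the hormone signals that set sex-biased expression, beside the lower Socs2, may be a source, as a hypothesis that no measurement here tests.

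Among control arrays, replicate 2 stood apart in the mean of triglyceride and lipid droplet genes (-0.55 against -0.28 to -0.24, gap 0.880 of the range), Xist (0.26, gap 0.867), Orm3 (-0.08 against -0.81 to -0.75, gap 0.918) and Mcm2 (-0.05, gap 0.905). Replicate 4 stood apart in markers of recruited macrophages (0.02 against 0.24 to 0.26, gap 0.898), stellate cell genes (-0.13 against 0.10 to 0.11, gap 0.955) and Cd74 (0.16 against 0.90 to 1.01, gap 0.867). Replicate 1 stood apart in Car3 (2.52 against -3.24 to -2.43, gap 0.858), Jun (2.17 against -2.32 to -1.58, gap 0.834), Il1r1 (-0.36 against 1.67 to 1.91, gap 0.893) and Got1 (0.25 against 1.08 to 1.12, gap 0.957). Replicate 3 stood apart in Acot3 (-0.63, gap 0.839) and Sdhb (-0.15 against -0.12 for the others, gap 0.961).

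Among HFD arrays, replicate 4 stood apart in markers of recruited macrophages (0.25 against -0.29 to -0.16, gap 0.771), cell cycle genes (0.24 against -0.15 to -0.05, gap 0.741) and Gpnmb (0.68 against -0.15 to 0.03, gap 0.786). Replicate 5 stood apart in heat shock genes (-0.53 against 0.08 to 0.33, gap 0.712), Acat1 (0.08 against 0.40 to 0.52, gap 0.738) and its distance from the mean of the other HFD arrays over all probe sets (0.345 against 0.234 to 0.266, gap 0.712). Replicate 3 stood apart in Sqle (-0.69 against -1.71 to -1.44, gap 0.737) and replicate 2 in Bmp2 (-1.05 against -0.29 to -0.12, gap 0.811). Of 8981 probe sets with no single gene symbol, which entered no named result, 151 were past the threshold when every probe set was tested, 77 higher and 74 lower in HFD.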

How the results depend on the processing

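Leaving out HFD replicate 5 with control replicate 1, and leaving out probe sets that can bind related transcripts, were chosen after seeing the data. The 917 genes became 385 (without control replicate 2) to 996 (without HFD replicate 4) with 1 array left out, 245 at an adjusted p under 0.01, 596 with a change of at least 1.5-fold and 366 with an unmoderated test, 343 of them among the 917. The stricter p and the fold limit lower the count by construction. For the unmoderated test and the arrays left out the cause was not tested. Every other setting gave 706 to 1363 genes, the most with every probe set on its own, and the share of higher genes stayed between 58.6% and 69.7%. The 20 lists became 0 with an estimated correlation, whose lowest adjusted p was 0.0824, 19 with fry, 18 to 21 with 1 array left out and 18 to 22 otherwise. Fry lost fatty acid synthesis (0.0668), endothelial markers (0.0579) and the interferon response (0.0668), and gained apolipoproteins (0.0103) and adipose markers (0.0385). The 16 lists past the exact test became 0 to 0 with 1 array left out, since the smallest p then rises to 0.0286 or 0.0357, while 16 to 20 lists still had no overlap. With medians in place of means 18 lists passed. Single genes were run under up to 17 alternatives, without the stricter p, the fold limit and the unmoderated test. Of 110 named genes past the threshold 63 stayed past it under each of these and 47 did not under 1 or more. Over all 3200 combinations of a named gene and such an alternative, 2871 kept their side of the threshold, 252 lost a call and 77 gained one. Over 912 combinations of a list and an alternative, these numbers were 866, 34 and 12. No called gene or list changed direction. No paired analysis was possible because the labels give the groups no shared replicate numbers. The number of arrays limits what can be called, and signal over background cannot be judged from centred values.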

Other observations

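Clock genes differed between the groups. Of 18 measured members of the circadian clock list 4 rose and 1 fell in HFD. Nr1d2, a nuclear receptor of the clock's negative arm, rose by 1.00 ± 0.17, Hlf, a transcription factor of clock output, by 0.99 ± 0.19 and Npas2, a partner of the core clock activator, by 0.90 ± 0.16, while Nfil3, a repressor of clock output, fell by 0.59 ± 0.10 (log2, 4 control and 5 HFD arrays). The camera adjusted p was 0.00138, with an adjusted p = 0.179 with an estimated correlation, and adjusted over the list alone 7 rose and 1 fell. The array means of the list overlapped between the groups (exact permutation adjusted p = 0.0762). The count of 4 was 2 without control replicate 2, averaging all probe sets brought Npas2 to 0.57, and the labels used here give no time of day for the samples.

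Growth signalling genes moved in both directions. Of 16 measured members of the list of insulin and growth hormone signalling, Pik3r1, a regulatory subunit of a lipid kinase below the insulin receptor, rose by 1.28 ± 0.20, and Socs2 (-2.98 ± 0.50), Akt1 (-0.87 ± 0.18) and Igfals, a carrier of circulating growth factor (-0.82 ± 0.17), fell. The list was not called (camera adjusted p = 0.292), and its array means did not overlap (exact permutation p = 0.0159, adjusted p = 0.0476). Fry did not call it (adjusted p = 0.150), and adjusted over the list alone 2 rose and 5 fell. Without control replicate 1, 2 or 3 or HFD replicate 3 only 1 member fell. With probe sets averaged Pik3r1 stood at 0.74 and Akt1 at -0.33. Of 13 genes of p53 targets and apoptosis, Ccng1 (0.81 ± 0.15) and Casp8 (0.46 ± 0.09) rose, Mdm2 stood at 0.38 ± 0.13 and Bcl2l11 at -1.59 ± 0.56, and the list was not called (camera adjusted p = 0.449, with 2 higher adjusted over the list alone).

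Arrays within the HFD group differed from each other. Apoa4 stood at 0.64 and 0.51 in HFD replicates 1 and 2 and at 2.29, 2.52 and 1.82 in HFD replicates 3, 4 and 5, and Cidec at 0.44 and 0.66 against 2.13, 2.41 and 1.79. These genes were picked after their values were seen, and Hsd3b3 ran the other way, at 2.01 and 1.51 against 0.76, 0.44 and 1.01. Some list means, also picked after they were seen, split in the same way. The mean of triglyceride and lipid droplet genes was -0.05 and 0.05 against 0.61, 0.59 and 0.52. The means of the sex-biased lists, given above, split likewise. The cholesterol synthesis mean did not, at -0.67 and -0.48 against -0.27, -0.16 and -0.79. Over all probe sets HFD replicates 1 and 2 correlated at 0.454 and replicates 3 and 5 at 0.494, while replicate 4 correlated at -0.015 to 0.152 with the other HFD arrays, so that no such split held over all probe sets. On the first principal component, which held 36.0% of the variance, control arrays lay between -38.4 and -22.7 and HFD arrays between 6.27 and 50.6. The groups overlapped on the second component (22.8%), where control arrays rose from -13.9 (replicate 1) to 25.6 (replicate 4) in the order of their numbers. HFD arrays lay between -32.9 (replicate 2) and 37.2 (replicate 5), not in full order. Whether this follows a batch cannot be told from the labels.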
